A study of Homo sapiens with 12 samples.

How the data were processed

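The series holds RNA-seq of 6 human cell types grown in culture, with 2 libraries per type and 12 in all. RNA was isolated with a column kit after the cells had been detached with trypsin, and libraries were made with standard Illumina protocols, per the labels. Per the submitters' processing notes, base calling used CASAVA 1.4, reads were aligned to GRCh37 with TopHat2 2.0.5, and reads per gene were counted with HTSeq. The authors deposited 1 table of genes with a read count and a TPM value (a level in transcripts, a read count divided by transcript length and scaled to a common total) for each library. A further deposited table gives the TPM of protein-coding genes, and its values were identical to those of the first over its 22074 genes. Its columns of MYO, MFB, CHON and FDC carry the letter o for the values of replicate 1 and n for those of replicate 2. The ESF and DSC columns carry numbers instead, and the meaning of the letters is not given. The read counts were deposited as whole numbers and were used as such, and the deposited TPM values were used for levels, distances and shared expression.

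Of the 60379 lines of the gene table, 6 were blank. The 514 genes of X inactivation or of chromosome Y were removed before any test, because some of the cells come from people. The 59865 genes that remained each had a deposited symbol, which is used here, and 21999 of them were protein-coding. Every per-sample column was read. The annotation at hand was for GRCh38 while the study used GRCh37, so it was used for gene overlap and GC content and no coordinates are given.

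Counts per library ran from 23527023 to 65655292, apart from the count column of CHON replicate 2 with 21430992. That column held no count above the one of CHON replicate 1 and differed from it by less than sampling noise would give for a separate library, with a chi-square per gene of 0.339 among genes with at least 50 counts. The TPM column of CHON replicate 2 came from a different library. Multiplying TPM by transcript length gave back 55481950 counts for it, whole to within 0.01 in 99.97% of genes, and gave back the deposited counts of the other 11 libraries. Tests on counts therefore used 1 CHON library, and TPM levels used both.

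The replicates of each group were compared gene by gene with a chi-square against sampling noise. The chi-square per gene was 203 in MFB, 216 in FDC and 220 in MYO, and 4.25 in ESF and 1.92 in DSC. Among genes with up to 10 counts, even counts made up 49.2% to 51.3% of genes in the ESF and DSC libraries and 36.4% to 39.2% in the others, as when the 2 reads of a pair are counted one by one, and sampling noise then allows a chi-square per gene of up to 2. The even counts in DSC gave an estimate of 1.57, and 1.92 lies between these, with 2.61 in genes with over 10000 counts. The DSC replicates thus lay close to sampling noise, and they were summed and counted as 1 sample, although the series describes 2 biological replicates for each type. The even counts in ESF gave an estimate of 1.62, below its 4.25, and ESF was kept as 2 libraries. The spread between the ESF libraries may still be technical. The design fixed beforehand had all 12 libraries, and the test was made on 10: 2 each of MYO, MFB, FDC and ESF, 1 of CHON and 1 of DSC. Both lone samples were assumed to vary like the other groups. For CHON the recovered reads of replicate 2 differed from replicate 1 with a chi-square per gene of 407, the highest of the groups. The median absolute log2 difference was 0.498 there and 0.486 in MFB. With the recovered reads as a second library the common dispersion, the spread shared by all genes, was 0.221 against 0.182, so the spread assumed for CHON may be too small.

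Differences between groups were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, a robust quasi-likelihood fit of the 6 group means, two-sided tests of contrasts of those means, and Benjamini-Hochberg adjustment over the 21594 genes tested, with a threshold of 0.05. For a comparison of 1 type with the others, ESF and DSC were first averaged, since they come from 1 line. The 31 gene lists fixed before the data were examined were tested with camera in limma 3.58.1, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists within a comparison. An estimated correlation was the alternative. With it, 3 calls held in DSC against ESF (decidual markers, progestin and glucocorticoid response, IGF axis), 3 in the endometrial comparison (endometrial stromal identity, matrix proteases and inhibitors, IGF axis), 2 in MYO (HOXD cluster, endometrial stromal identity), 4 in MFB (matrix proteases and inhibitors, p53 targets, IGF axis, uterine contraction-associated genes) and 0 in CHON and in FDC. Counts of list members are given over all genes tested and adjusted over the list alone. Of the 626 genes in the lists, 57 were not found among the genes tested and do not enter.

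The gene lists, the comparisons, the tests, the named-gene rule and a first set of alternatives were chosen before the data were examined. Genes named as top changes are protein-coding, have an adjusted p under 0.05, lie in every library of 1 side above or below every library of the other, and have a mean of at least 5 CPM, counts scaled to a common library total, in the higher side. For DSC against ESF the 12 with the largest positive and the 8 with the largest negative log2 difference were taken, and 8 and 4 for every other comparison. PRL, IGFBP1, FOXO1, PGR, ESR1, HAND2, HOXA10 and HOXA11 were named for both endometrial comparisons whatever their result, TERT for every group, and up to 4 members with the smallest adjusted p for each called list and for the list of the type itself.

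On simulated data with the same groups and depths, where 2-fold and 4-fold changes were put into 200 genes, the test recovered 3% of the 2-fold and 41% of the 4-fold changes in DSC against ESF, 9% and 54% in CHON, and 11% to 29% and 73% to 80% in the other comparisons. Of the calls made, 1.89% to 8% were unchanged genes. camera called 2 of 2 shifted lists and 0 of 28 unchanged ones in each comparison. The simulated genes were drawn independently and had no shift shared between replicates. The simulation therefore cannot show how often camera calls unchanged lists where genes vary together. Each gene was also given the same spread in all groups, while in the data the ESF replicates lay far closer than those of MFB, FDC and MYO. The shares recovered and wrongly called may thus differ in the real tests.

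A group with no counts of a gene was given a floor of 3 counts over the group, or 6 counts in ESF and DSC, and a fold against it is written as at least that size. These floors were 0.0266 CPM in FDC, 0.0387 in MFB, 0.0405 in MYO, 0.0712 in ESF, 0.0729 in CHON and 0.0813 in DSC. They cover counting error only. For 1 type against the others, folds are given against the type nearest to it.

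Distances between types are 1 minus the Spearman correlation over the 12092 protein-coding genes with a TPM of at least 3 in 1 or more libraries. A neighbour-joining tree was drawn with ape 5.8.1 on the Euclidean distance of square-root TPM with 1000 bootstraps over genes. A gene was counted as expressed in a type at a TPM of at least 3 in both of its replicates.

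The replicate numbers carry information in part of the series. In MYO, MFB, CHON and FDC they divide the libraries as the deposited letters o and n do. Across genes, the difference between replicate 2 and replicate 1 correlated between MYO, MFB, CHON (from TPM) and FDC at 0.560 to 0.691 over their 6 pairs, and at -0.00634 to 0.0699 for pairs with ESF or DSC. A fit with the replicate number as a block among these 4 types was therefore added, and its value is given beside a result where it ends the call of a list, makes one of the genes named beforehand pass, or moves a count by over 1.5 times. The alternatives written beforehand were other normalizations (RLE), other tools (DESeq2 1.42.0 and limma-voom), other filters, protein-coding genes only, a 2-fold minimum, a block on replicate number, other weightings of the types, other distance measures and TPM limits, and leaving out each library. Chosen after seeing the data were the block among 4 types, the recovered reads of CHON replicate 2 as a second library or in place of the first, both together, the deposited CHON replicate 2 counts as a second library, only replicate 1 or only replicate 2 of the 4 types, a rescaled FDC replicate 2 (its TPM values sum to 862123 after the exclusions), DSC as 2 libraries, and ESF also as 1 library with edgeR or DESeq2. Raw reads, splicing and variants were not analysed here. Values were read and drawn with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.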

Results

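The series measured RNA in 6 human mesenchymal cell types grown in culture, 2 libraries each. ESF were endometrial stromal fibroblasts of the hTERT line CRL-4003, and DSC were the same line after decidualization in vitro. MYO were cultured myometrial cells and FDC cultured follicular dendritic cells, with no line given. MFB were prostate stromal cells of the line WPMY-1, immortalised with SV40 large T, and CHON were chondrocytes of the hTERT line CHON-002. The libraries held 23527023 to 65655292 counts. Levels are given as TPM, mean ± SD with n = 2, and for DSC as the mean alone. The SD of ESF may measure technical spread only, for the reason given next.

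The 2 DSC libraries were close to the sampling noise of reads counted in pairs, with a chi-square per gene of 1.92 against 203 in MFB. The share of even counts gave an estimate of 1.57 for that noise. They were counted as 1 sample, although the series text names 2 biological replicates. The ESF libraries were nearly as close, at 4.25, with an estimate of 1.62 from even counts. In genes with 50 to 300 counts ESF lay at 1.76 and DSC at 1.67, while ESF lay higher in genes with more counts. ESF was kept as 2 libraries, so its SDs and the p-values that rest on it may measure technical spread. With ESF also as 1 library, edgeR called 0 genes in DSC against ESF. The spread was estimated over all groups together. The common dispersion, its value shared by all genes, was 0.182 in the main fit and 0.0483 with a replicate block among 4 types. With only ESF and DSC in the fit it was 0.00134. The p-values of DSC against ESF thus rest largely on replicate differences in other cell types, not on variation between decidualized cultures. The count column of the second CHON library was above the first in no gene, and tests used the first alone. ESF and DSC may also have differed from the other 4 types in how reads had been counted. Among genes with up to 10 counts, 49.2% to 51.3% of counts were even in ESF and DSC and 36.4% to 39.2% elsewhere. Replicate numbers were paired across MYO, MFB, CHON and FDC, with shifts that correlated at 0.560 to 0.691. A value "with a replicate block" is printed where that block ended a call of a list, made one of the genes chosen beforehand pass, or moved a count.

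The first question was what decidualization changes in ESF. The hormone gene SST, silent in ESF, reached a TPM of 485 in DSC, at least 5045-fold more (adjusted p = 0.010). Other genes with no counts in ESF were the interferon-induced IFI44L (34.8 in DSC, at least 522-fold), the matrix proteoglycan OMD (4.16, at least 172-fold), and the steroid enzyme HSD17B6 (8.02, at least 142-fold). The chemokine receptor CXCR7 (5.29, at least 130-fold), the retinoid transporter ABCA4 (5.68, at least 100-fold), the ligand WNT4 (4.93, at least 76.5-fold) and the cannabinoid receptor CNR1 (2.29, at least 71.0-fold) had none either. The alcohol dehydrogenase ADH1B rose from 0.0433 ± 0.00595 to 65.4 (log2 difference 10.70, adjusted p = 0.0067). The growth factor IGF1, whose gene overlaps another on the opposite strand over 82% of its length and whose level is thus uncertain, rose from 0.220 ± 0.153 to 157 (9.62, adjusted p = 0.0050). The hormone-induced repressor ZBTB16 went from 0.0854 ± 0.0784 to 30.5 and the cation transporter SLC47A1 from 0.0154 ± 0.0217 to 4.72.

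Among the genes that fell, the collagenase MMP1 went from 1409 ± 24.1 to 5.35 (log2 difference -7.89, adjusted p = 0.0048), the stromelysin MMP10 from 291 ± 2.45 to 0.232 (-10.13, adjusted p = 0.0037) and MMP3 from 23.7 ± 0.525 to 0.121 (-7.41, adjusted p = 0.046). The protease receptor F2RL1 went from 78.2 ± 0.277 to 0.398 and the amino acid transporter SLC6A15 from 21.8 ± 1.65 to 0.115. No counts were left in DSC of the membrane protein FER1L6 (5.34 in ESF, at least 423-fold less), the ciliary TTC29 (4.72, at least 103-fold) and the urea transporter SLC14A1 (7.03, at least 84.1-fold).

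**Figure D1:**
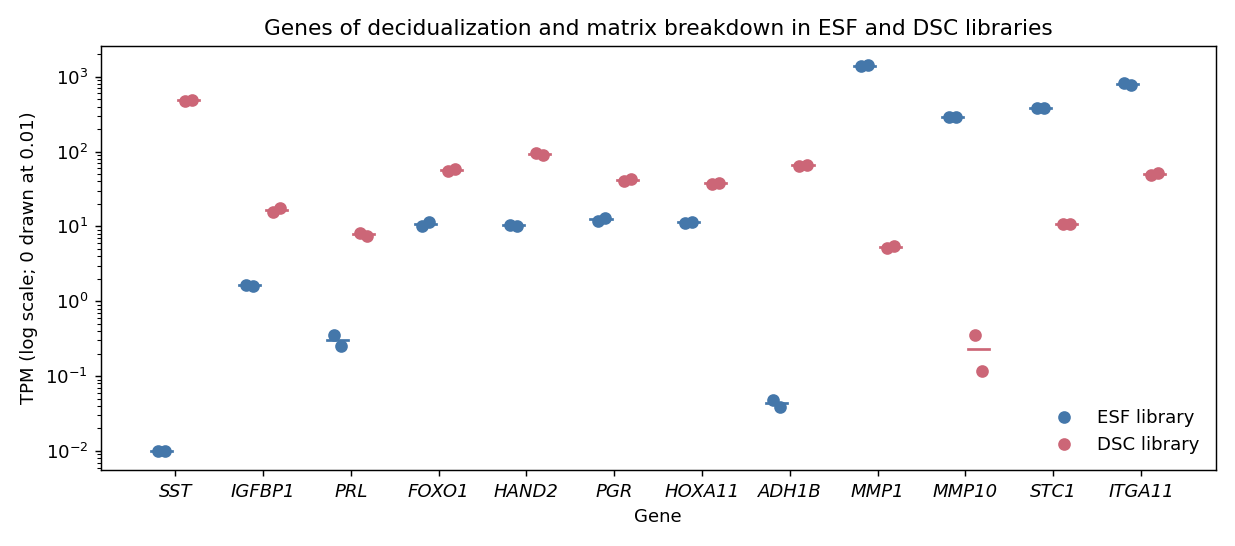
TPM on a log axis of 12 genes in each ESF and DSC library, with points for libraries and lines for means. SST went from 0 to 485 and MMP1 from 1409 to 5.35.

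The decidual hormone PRL rose from 0.302 ± 0.0705 to 7.91 (log2 difference 4.85, adjusted p = 0.047), its partner IGFBP1 from 1.63 ± 0.0518 to 16.6 (3.50, adjusted p = 0.025). The transcription factors FOXO1 and HAND2 rose from 10.9 ± 0.991 to 56.8 (2.54, adjusted p = 0.035) and from 10.3 ± 0.404 to 92.4 (3.31, adjusted p = 0.0048). The progesterone receptor PGR (12.5 in ESF, 42.0 in DSC, adjusted p = 0.15), HOXA10 (12.8 and 48.0, adjusted p = 0.26) and HOXA11 (11.3 and 37.7, adjusted p = 0.054) did not pass. With a replicate block all 3 passed, at 0.014, 0.020 and 0.0065. The oestrogen receptor ESR1 (0.619 and 0.409, adjusted p = 0.81) did not pass.

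Of 22 decidual markers tested 12 rose, 1 fell and 9 did not pass (17 rose and 3 fell adjusted over the list alone), with a camera adjusted p of 7.3e-16 and 0.028 with an estimated correlation. They included the amine oxidase MAOA (0.133 ± 0.00577 to 3.94) and the WNT inhibitor DKK1 (97.1 ± 2.09 to 788). The median log2 difference was 3.24, or 3.11 with floors for groups at 0. Of 16 progestin and glucocorticoid response genes 5 rose and 11 did not pass (11 rose adjusted over the list alone, adjusted p = 1.6e-09, and 0.035 with an estimated correlation). They were led by the secreted CRISPLD2 (7.03 ± 0.829 to 1261), the chaperone FKBP5 (2.65 to 12.3), CEBPD (2.17 to 24.7) and the kinase SGK1 (97.3 to 357). Of 17 IGF axis genes 7 rose and 10 did not pass (8 adjusted over the list alone, adjusted p = 8.2e-07, and 0.046 with an estimated correlation). Among them were the binding proteins IGFBP2 (0.184 to 5.90) and IGFBP3 (37.9 to 1216) and the adaptor IRS2 (6.15 to 32.7).

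Inflammatory and NF-kappaB genes went down as a list: of 25, 1 rose, 3 fell and 21 did not pass (1 and 14 adjusted over the list alone), adjusted p = 5.3e-06, and 0.29 with an estimated correlation. The cytokines LIF (3.34 to 0.282) and IL1B (log2 difference -2.14) and the chemokine CXCL5 (0.141 to 0) fell while the chemokine CCL2 rose (7.35 to 84.4). Of 30 proliferation genes only the replication factor MCM4 fell (155 to 43.2) and 29 did not pass (1 adjusted over the list alone), with a median of -0.71 and adjusted p = 0.00012, and 0.48 with an estimated correlation. cAMP response genes (3 rose and 1 fell of 18; 6 and 1 adjusted over the list alone, adjusted p = 0.00040, and 0.29 with an estimated correlation) included the phosphodiesterases PDE7B (3.57 to 25.7) and PDE4D (9.26 to 94.3), the coactivator PPARGC1A (0.199 to 14.1), and STC1, which fell from 383 ± 4.99 to 10.7. TGF-beta response genes (2 rose and 2 fell of 18; 2 and 8 adjusted over the list alone, adjusted p = 0.0026, and 0.47 with an estimated correlation) included the falling integrin ITGA11 (803 to 50.5) and regulator BHLHE40 (24.9 to 5.63) and the rising matrix proteins TGFBI (154 to 3820) and LTBP1 (191 to 979).

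Further lists passed with few single genes. Endometrial stromal identity had 1 riser of 15 (6 and 1 faller adjusted over the list alone, adjusted p = 3.5e-05, and 0.065 with an estimated correlation). Interferon-stimulated genes (3 of 29 rose, 7 adjusted over the list alone, adjusted p = 0.0066, and 0.10 with a replicate block) included IFI6 (5.30 to 26.6) and USP18 (0.0203 to 0.441). WNT genes (4 of 23, 5 and 1 adjusted over the list alone, adjusted p = 0.016, and 0.18 with a replicate block) included the antagonist SFRP1 (0.0711 to 17.2) and the agonist RSPO3 (0.143 to 11.8). Smooth muscle genes (2 of 20, 4 adjusted over the list alone, adjusted p = 0.016, and 0.13 with a replicate block) were ACTG2 (0.339 to 15.7) and SORBS1 (0.132 to 6.86). The FDC list (3 of 16, 5 adjusted over the list alone, adjusted p = 0.016, and 0.081 with a replicate block) held ENPP2 (0.389 to 1.34), IL15 (7.61 to 45.2) and C3 (0.542 to 7.83). Collagen and matrix genes (4 of 29, 8 and 2 adjusted over the list alone, adjusted p = 0.045, and 0.20 with a replicate block) held COL15A1 (0.219 to 21.7), FBN1 (510 to 2377), FBN2 (105 to 399) and COL14A1 (4.44 to 113). Cholesterol synthesis (0 of 21, 0 adjusted over the list alone, median -0.71, adjusted p = 0.0079) and the HOXA cluster (0 of 11, 3 rose adjusted over the list alone, adjusted p = 0.0078) passed. Adipogenic and pericyte genes (0 of 13, 4 and 1 adjusted over the list alone, adjusted p = 0.010) and endothelial genes (2 fell of 13, PECAM1 from 1.06 and ROBO4 from 0.376 to 0; 1 and 2 adjusted over the list alone, adjusted p = 0.013) also passed. With an estimated correlation these lists had adjusted p from 0.22 to 0.60. The endothelial call was also lost with a filter of at least 1 CPM in 2 libraries. With the recovered CHON reads and the block, the adipogenic and pericyte call was lost, here and in the comparison of ESF and DSC with the other types. Matrix proteases did not pass as a list (3 rose and 6 fell of 24, adjusted p = 0.099).

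In all, edgeR called 636 of 21594 genes, 391 higher and 245 lower in DSC. The number depended on the spread assumed, and was 1771 with DESeq2 (875 higher and 896 lower), 1026 with limma-voom, 2039 with a replicate block and 2198 with DSC as 2 libraries (1098 and 1100). With DESeq2 and with DSC as 2 libraries the majority of higher genes was lost. It was 0 with ESF also as 1 library or without ESF replicate 1 or 2, when every gene call named above was lost and, of the lists, the collagen and matrix genes. With ESF also as 1 library, edgeR still gave 1914 genes at an unadjusted p under 0.05, and DESeq2 called 878.

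The second question was what sets the endometrial cells, ESF and DSC together, apart from the other 4 types. The adrenergic receptor ADRA2C had a TPM of 4.22 ± 0.192 in ESF and 217 in DSC against 0.124 or less elsewhere (log2 difference 10.81, adjusted p = 6.1e-05). The progesterone receptor PGR had 12.5 and 42.0 against 1.76 ± 1.06 in MYO, the next type (8.75, adjusted p = 0.00013). The nuclear protein MUM1L1 (1.82 and 37.8), the small GTPase DIRAS2 (1.29 and 12.6), and the calcium channel CACNA1H (20.7 and 19.3, FDC 8.36) were higher. The transporter SLC35F3 (5.30 and 2.20), the synaptic adhesion gene SLITRK4 (55.2 and 64.7), the fusion protein DCSTAMP (36.4 and 0.369) and renin, REN (2.25 and 27.5), were higher as well. The ion channel PIEZO2, the ankyrin-repeat gene ANKRD29 (74.6 in FDC), the scaffold gene MPP2 and CCDC152, which overlaps another gene over 42%, had no counts in either. PRL (9.17, adjusted p = 0.0012), IGFBP1 (6.49, adjusted p = 0.00031), FOXO1 (3.93, adjusted p = 0.00024), HAND2 (2.57, adjusted p = 0.00010), HOXA10 (3.01, adjusted p = 0.0065) and HOXA11 (5.35, adjusted p = 0.00019) were higher on average. However, IGFBP1 was at 17.4 ± 10.1 in CHON and HAND2 at 99.2 in FDC. ESR1 did not pass (-0.43, adjusted p = 0.29).

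Endometrial stromal identity genes were higher in 13 of 15 (13 adjusted over the list alone, adjusted p = 3.7e-12, and 0.0496 with an estimated correlation), with the positional factors HOXD11 (7.93), HOXD10 (8.88) and EMX2 (7.27). This list was not particular to the endometrial cells. In MYO against the other types it was also called higher (camera adjusted p = 3.0e-09), as were the HOXA, HOXB and HOXD clusters. Matrix proteases were higher in 16 of 24 (18 adjusted over the list alone, adjusted p = 1.7e-10, and 0.0496 with an estimated correlation): the aggrecanase ADAMTS4 was at 28.6 ± 0.590 in ESF and 138 in DSC, and MMP11 at 1265 ± 47.4 and 14.1. IGF axis genes were higher in 11 and lower in 1 of 17 (11 and 2 adjusted over the list alone, adjusted p = 5.5e-07, and 0.0496 with an estimated correlation). They included the protease PAPPA (98.5 and 590), IGFBP5 (731 and 510, FDC 3083) and IGF2 (463 and 470), which shares 74% of its length with a gene on the same strand. cAMP response genes were higher in 14 and lower in 1 of 18 (the same adjusted over the list alone, adjusted p = 1.1e-07, and 0.15 with an estimated correlation). The G-protein regulator RGS2 stood at 149 ± 2.88 and 166 against at most 7.40.

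Proliferation genes were lower in 13 of 30 (24 adjusted over the list alone, adjusted p = 2.0e-07, and 0.46 with an estimated correlation), with PCNA at a log2 difference of -1.10. Cholesterol synthesis genes were lower in 9 of 21 (15 adjusted over the list alone, adjusted p = 1.1e-05, and 0.43 with an estimated correlation), with LSS at -1.29. Decidual markers (10 higher of 22; 12 and 3 lower adjusted over the list alone, adjusted p = 1.3e-05, and 0.13 with an estimated correlation) included HSD11B1 (8.27 and 86.7) and BMP2 (29.2 and 9.85). The HOXD (6 of 9, adjusted p = 1.4e-06), HOXA (7 and 1 of 11, adjusted p = 7.9e-05) and HOXB (4 of 8, adjusted p = 0.0030) clusters passed, with 6, 8 and 1, and 5 genes adjusted over the list alone. Collagen and matrix genes (14 and 1 of 29, adjusted p = 0.00025, COL1A1 41333 and 56761) and antigen presentation (7 of 16, adjusted p = 0.0020, HLA genes that share reads) passed, with 16 and 3, and 7. So did adipogenic and pericyte genes (7 of 13, adjusted p = 0.0025, PDGFRB 3697 and 1477) and progestin response (7 and 1 of 16, adjusted p = 0.015, and 0.13 with a replicate block), with 8 and 1, and 9 and 2. With an estimated correlation these ran from 0.062 to 0.46. edgeR called 5140 genes, 2777 higher and 2363 lower, but DESeq2 called more lower than higher (3123 higher and 3669 lower). edgeR called 9306 with a replicate block, 8102 with DSC as 2 libraries and 2529 with ESF also as 1. Without ESF replicate 1 the number was 2437 and without ESF replicate 2 it was 2458. The possible difference in read counting lies along this same comparison.

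The next question was what marks MYO. The largest differences included the cancer-testis genes MAGEA6 (43.9 ± 0.718, at least 971-fold), CTAG2 (40.5 ± 6.86, at least 843-fold), SAGE1 (4.86 ± 0.390, at least 335-fold), MAGEA1 (46.3 ± 8.60) and MAGEC2 (90.6 ± 0.542), some of which share reads with close copies. The germ-cell gene RNF17 (13.4 ± 0.837), the forkhead factor FOXR2 (3.83 ± 0.280, at least 258-fold) and the keratin KRT81 (116 ± 23.7, 696-fold above MFB) were also restricted to MYO. The glucose transporter SLC2A8 (at least 174-fold), C8orf42 (at least 182-fold), the neuronal DPYSL4 (at least 47.7-fold) and BEX1 (at least 3.03-fold) had no counts. TERT had a TPM of 1051 and 185 in the MYO libraries, against 272 to 1128 in the libraries of the hTERT lines. No line is given for MYO, so traits of this culture cannot be told from traits of myometrial cells.

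The oxytocin receptor OXTR was at 367 ± 167, 1.61-fold above ESF (log2 difference 4.58, adjusted p = 0.0012), and the muscle actin ACTG2 at 160 ± 114 (4.98, adjusted p = 0.0011). The muscle cofactor MYOCD was at 42.6 ± 36.7 with DSC higher at 55.9, PDLIM3 at 22.2 ± 16.9 and the calcium-pump regulator PLN at 6.20 ± 8.51. Smooth muscle genes were higher in 9 of 20 (10 adjusted over the list alone, adjusted p = 0.0059, and 0.55 with an estimated correlation), a call that was lost without MYO replicate 2. Uterine contraction genes were not called (5 higher and 4 lower of 16; 5 and 6 adjusted over the list alone, adjusted p = 0.89). Against the mean of the others on a log scale, the cyclooxygenases PTGS1 (64.0 ± 2.20, ESF 616) and PTGS2 (3.67 ± 0.106, CHON 28.8) were higher and the endothelin receptor EDNRA (1.24 ± 0.378, MFB 0.741) was lower. On the TPM scale ESF lay above MYO in PTGS1, and CHON above MYO in PTGS2.

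All 9 HOXD genes were higher (9 adjusted over the list alone, adjusted p = 5.9e-14, and 0.043 with an estimated correlation). So were 12 of 15 endometrial identity genes, with 1 lower (the same adjusted over the list alone, adjusted p = 3.0e-09, and 0.043 with an estimated correlation), among them HOXD11 (19.0 ± 1.72) and WT1 (3.04 ± 0.671, DSC 5.48). HOXB genes (7 of 8; 8 adjusted over the list alone, adjusted p = 1.2e-06, and 0.058 with an estimated correlation) included HOXB7 (10.4 ± 0.186). Inflammatory genes (14 higher and 4 lower of 25; 16 and 4 adjusted over the list alone, adjusted p = 0.00010, and 0.45 with an estimated correlation) included IL1B (32.7 ± 2.68), the chemokine CXCL6 (57.8 ± 36.7) and the growth factor CSF3 (9.67 ± 9.65). Endothelial genes (4 of 13; 6 and 1 adjusted over the list alone, adjusted p = 0.0052, and 0.27 with an estimated correlation) included the receptor TIE1 at 148 ± 73.4, 148-fold above ESF. IGF axis genes (2 higher and 8 lower of 17; 4 and 9 adjusted over the list alone, adjusted p = 0.0053, and 0.055 with a replicate block) included the insulin receptor INSR at 0.00960 ± 0.00980. Proliferation (11 of 30, 18 adjusted over the list alone, adjusted p = 6.1e-07) and HOXA genes (9 of 11, 9 and 1 adjusted over the list alone, adjusted p = 0.00040) were higher. A further 5 lists had adjusted p from 0.036 to 0.047 and lost the call with a replicate block. They were TGF-beta response (6 and 2 of 18; 8 and 2 adjusted over the list alone, 0.064 with the block), epithelial genes (5 and 1 of 13; the same adjusted over the list alone, 0.11), cAMP response (1 and 6 of 18, the same, 0.10), the FDC list (2 and 5 of 16, the same, 0.17) with CLU at 22.5 ± 4.88 and leukocyte genes (4 of 12; 5; 0.078) with CSF1R at 16.7 ± 7.32. With an estimated correlation the lists given here without that value ran from 0.20 to 0.73. edgeR called 4169 genes, 2529 higher and 1640 lower. The number was 6768 with a replicate block, 2776 with ESF also as 1 library, 2371 without MYO replicate 2, 2674 without MYO replicate 1, 2758 without ESF replicate 1 and 2757 without ESF replicate 2.

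For MFB the question was the same. The ephrin receptor EPHA7 (13.2 ± 0.303, 120-fold above FDC), the ubiquitin adaptor KLHL4 (5.68 ± 3.08), the germ-cell gene TDRD1 (12.6 ± 0.719), and the forebrain factor FOXG1 (31.4 ± 7.70, 16.1-fold above MYO) were high relative to the others. So were the glycosyltransferase GALNT13 (22.7 ± 7.87), ASB5 (78.1 ± 3.21, 31.5-fold above CHON), the phosphatase subunit PPP2R2B (30.7 ± 18.8) and TCF21 (3.94 ± 1.20, overlapping another gene over 30%). The growth factor BMP2 (at least 59.7-fold), the calcium-binding CALB2 (at least 8.79-fold) and the endocytic AMPH (at least 1.88-fold) had no counts, and the selenium-binding SELENBP1 was at 0.0206 ± 0.00915 against 14.4 or more.

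Replication genes were high and matrix genes low. Proliferation genes were higher in 29 of 30 (30 adjusted over the list alone, adjusted p = 4.4e-16, and 0.24 with an estimated correlation), with the helicase MCM2 at 356 ± 69.3, 2.40-fold above MYO, and PCNA at 229 ± 28.6. Collagen and matrix genes were lower in 20 and higher in 1 of 29 (22 and 1 adjusted over the list alone, adjusted p = 1.4e-11, and 0.24 with an estimated correlation). COL1A1 was at 7257 ± 176 against 16717 or more, THBS1 at 205 ± 52.5 and the microfibril gene FBN1 at 145 ± 4.29. Matrix proteases were lower in 13 of 24 (13 adjusted over the list alone, adjusted p = 4.5e-09, and 0.039 with an estimated correlation), among them MMP1 (-8.54) and the cathepsin CTSK (-4.29). p53 targets were lower in 14 of 22 (18 adjusted over the list alone, adjusted p = 1.7e-08, and 0.039 with an estimated correlation), with the cell-cycle inhibitor CDKN1A at 119 ± 53.5 against 459 or more. IGF axis genes (11 lower and 1 higher of 17; 14 and 1 adjusted over the list alone, adjusted p = 1.5e-07, and 0.039 with an estimated correlation) included IGFBP5 at 0.871 ± 0.722. Uterine contraction genes (10 lower and 1 higher of 16; the same adjusted over the list alone, adjusted p = 5.2e-07, and 0.039 with an estimated correlation) included PTGS1 at 0.151 ± 0.0147.

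HOXC genes were higher in 6 of 8 (6 adjusted over the list alone, adjusted p = 1.8e-05, and 0.052 with an estimated correlation), with HOXC8 at 7.21 ± 1.39. HOXA genes were higher in 9 of 11 (9 and 1 lower adjusted over the list alone, adjusted p = 0.00035), with HOXA13 at 12.8 ± 8.68, 14.8-fold above DSC. The FDC list was lower in 9 and higher in 2 of 16 (10 and 2 adjusted over the list alone, adjusted p = 6.8e-05, and 0.052 with an estimated correlation), with the adhesion gene VCAM1 higher at 7.38 ± 3.60. Smooth muscle genes were lower in 8 of 20 (9 adjusted over the list alone, adjusted p = 0.00035), with ACTG2 at -6.30 (0.350 TPM, ESF 0.339) and CNN1 at -3.46. Decidual markers (9 lower and 3 higher of 22, the same adjusted over the list alone, adjusted p = 0.0021), and HOXD genes (5 higher of 9, the same, adjusted p = 0.0031) passed. Adipogenic and pericyte (4 lower of 13, the same, adjusted p = 0.0059) and interferon-stimulated genes (6 lower and 1 higher of 29, 7 and 1 adjusted over the list alone, adjusted p = 0.0092) passed as well. WNT (8 lower and 4 higher of 23; 9 and 4 adjusted over the list alone, 0.070 with a replicate block), chondrocyte (6 and 2 of 26; 7 and 2; 0.094), inflammatory (8 and 3 of 25; 10 and 3; 0.059) and cAMP genes (6 and 1 of 18; 7 and 1; 0.094) had adjusted p from 0.024 to 0.046. With an estimated correlation the lists given here without that value ran from 0.11 to 0.46. TGF-beta response (1 higher and 5 lower of 18; 1 and 6 adjusted over the list alone, adjusted p = 0.073), with LTBP1 at -3.76 and LTBP2 at -4.02, hypoxia and glycolysis (adjusted p = 0.068) and neural genes (adjusted p = 0.10) were not called. edgeR called 4971 genes, 2701 higher and 2270 lower. It called 7529 with a replicate block, 3211 with ESF also as 1 library, 2915 without MFB replicate 1, 3185 without ESF replicate 1 and 3212 without ESF replicate 2.

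For CHON the cartilage proteoglycan ACAN stood at 24.6 ± 19.9, 1655-fold above MFB (log2 difference 11.87, adjusted p = 0.00017), and the cartilage regulator SOX9 at 15.4 ± 0.232, 7.09-fold above MYO (4.06, adjusted p = 0.00047). The guidance gene SEMA5B (7.72 ± 0.926, 380-fold above MFB), the kinase RIPK4 (10.7 ± 9.30), and the ETS factor ERG (32.4 ± 18.1, 559-fold above MFB) were also highest there. The same held for the Notch-like ligand DLK1 (619 ± 98.0, 51.5-fold above ESF), the homeobox gene GSC (13.1 ± 1.43), the potassium channel KCNF1 (5.36 ± 2.48) and SHISA2 (9.53 ± 6.96). The cell-cycle inhibitor CDKN2B (at least 73.8-fold), AMOT (at least 98.3-fold), the forkhead gene FOXF1 (at least 54.0-fold) and SLITRK5 (at least 58.0-fold) had no counts in the library tested.

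The chondrocyte list as such was not called (7 higher and 4 lower of 26; 9 and 4 adjusted over the list alone, adjusted p = 0.15), although COL11A1 (21.6 ± 18.7, DSC 27.2) and SOX5 (8.91 ± 4.43) passed. All 8 HOXC genes were higher (8 adjusted over the list alone, adjusted p = 1.6e-14, and 0.076 with an estimated correlation), with HOXC10 at 62.6 ± 0.418, 93.6-fold above MFB. IGF axis genes were higher in 6 and lower in 2 of 17 (9 and 2 adjusted over the list alone, adjusted p = 0.00014, and 0.11 with an estimated correlation), with IGFBP3 at 12426 ± 2378. BMP and activin genes were higher in 8 and lower in 1 of 22 (10 and 2 adjusted over the list alone, adjusted p = 0.00030, and 0.13 with an estimated correlation). They included the joint morphogens GDF6 (54.5 ± 4.41) and GDF5 (142 ± 83.2, overlapping another gene over 35%). Cholesterol synthesis was lower (1 of 21, 4 adjusted over the list alone, adjusted p = 1.5e-07, and 0.42 with an estimated correlation). So was endometrial identity (6 lower and 1 higher of 15, 8 and 1 adjusted over the list alone, adjusted p = 0.00014, and 0.11 with an estimated correlation), with GATA2 at 0.359 ± 0.430. The FDC list (4 higher and 1 lower of 16; 8 and 2 adjusted over the list alone, adjusted p = 0.0034), smooth muscle (4 higher of 20, 4, adjusted p = 0.0069) and proliferation genes (0 of 30, 0, adjusted p = 0.0225) passed too. So did HOXD (3 lower of 9; 4; adjusted p = 0.011, and 0.15 with a replicate block), inflammatory (7 higher of 25; 8 and 3; adjusted p = 0.028, and 0.24 with a replicate block) and HOXB genes (1 lower of 8; 1; adjusted p = 0.035, and 0.11 with a replicate block). With the FDC, smooth muscle and proliferation lists they ran from 0.13 to 0.74 with an estimated correlation. The inflammatory list had a median of 0.23 and a mean of -0.12, with a test direction of up, and included PTGS2 (28.8 ± 15.3). With the recovered reads in place of the first library, the direction of the smooth muscle (adjusted p = 0.54), inflammatory (adjusted p = 0.97) and proliferation lists (adjusted p = 0.20) reversed. With the recovered reads of the second library and the block, calls were lost for smooth muscle (0.79), the FDC list (0.12), inflammatory (0.87), proliferation (0.79), IGF axis (0.066), HOXB (0.086) and HOXD genes (0.26). edgeR called 1348 genes, 1008 higher and 340 lower. There were 2083 with a replicate block, 2546 with the recovered reads, 2091 with DESeq2 (1309 higher and 782 lower), 867 with ESF also as 1 library, 870 without ESF replicate 1 and 859 without ESF replicate 2.

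In FDC, the hormone receptor CCKAR (134 ± 17.5), the proteoglycan GPC3 (181 ± 73.4), the carboxypeptidase-like CPXM2 (210 ± 80.8, 988-fold above CHON), and the homeobox genes BARX1 (52.0 ± 10.9, 789-fold above CHON) and LHX8 (32.4 ± 0.662, 936-fold above MYO) were among the largest differences. The collagen COL6A6 (71.3 ± 34.2, 180-fold above ESF), the prostaglandin synthase PTGDS (426 ± 17.6, 3.23-fold above DSC) and the phosphodiesterase PDE9A (9.33 ± 0.615, 39.0-fold above ESF) completed them (adjusted p from 1.5e-05 to 0.00018). The telomerase gene TERT was at 0.00274 ± 0.00388, while ESF, DSC and CHON come from hTERT lines. HOXA9 (at least 543-fold), HOXA11 (at least 54.7-fold) and SLITRK4 (at least 2.74-fold) had no counts.

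Genes known from follicular dendritic cells were higher in 10 and lower in 2 of 16 (11 and 2 adjusted over the list alone, adjusted p = 4.5e-06, and 0.087 with an estimated correlation). The fixed list was longer than these 16, and members with too few counts in the series to be tested do not enter. The call thus rests on part of the list and does not by itself show the identity of the cells. Podoplanin, PDPN, was at 281 ± 5.56, clusterin, CLU, at 1413 ± 741, the lipid enzyme ENPP2 at 33.9 ± 0.103 and BST1 at 41.9 ± 9.93. Proliferation genes were lower in 28 of 30 (30 adjusted over the list alone, adjusted p = 9.2e-23, and 0.16 with an estimated correlation), with MCM4 at 33.6 ± 5.06 and E2F1 at 1.16 ± 0.603. Cholesterol synthesis genes were higher in 18 of 21 (19 adjusted over the list alone, adjusted p = 5.3e-11, and 0.17 with an estimated correlation), with LSS at 304 and MVD at 166 ± 30.8. Interferon-stimulated genes were higher in 18 of 29 (19 adjusted over the list alone, adjusted p = 1.6e-08, and 0.16 with an estimated correlation), with BST2 at 66.9 ± 31.5 and MX2 at 12.5 ± 4.44. Positional mesenchymal factors were higher in 26 and lower in 5 of 59 (27 and 7 adjusted over the list alone, adjusted p = 4.8e-06, and 0.16 with an estimated correlation), with PAX9 at 66.8 ± 21.4, 314-fold above MYO.

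**Figure D2:**
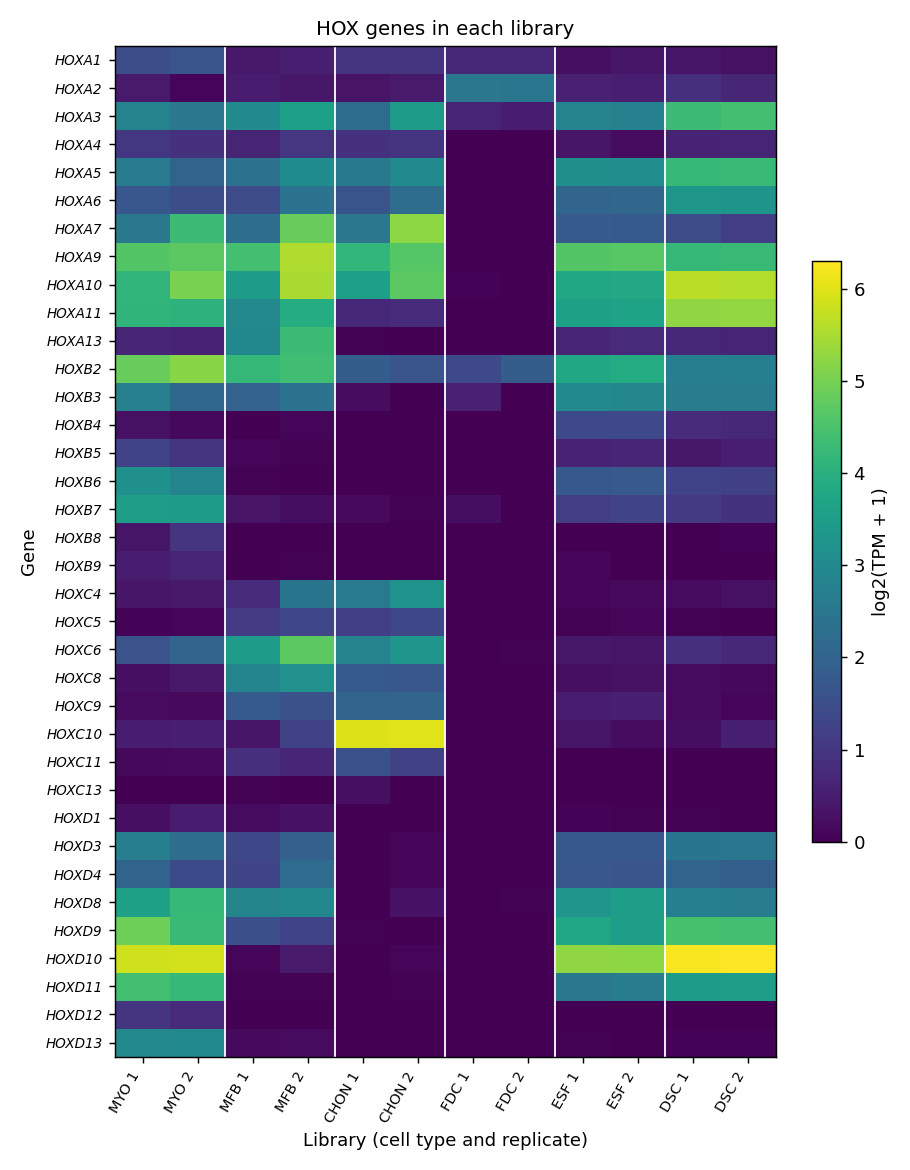
Heat map of log2(TPM + 1) of HOX genes in each of the 12 libraries. HOXA9 and HOXA11 were at 0 in FDC, and HOXC10 was at 62.6 TPM in CHON.

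In FDC the HOXA (9 lower and 1 higher, HOXA2, of 11, adjusted p = 2.7e-09) and HOXC clusters (6 lower of 8, adjusted p = 2.9e-06) were called, and so were HOXB (3 lower of 8, adjusted p = 0.018, and 0.062 with a replicate block) and HOXD (4 lower of 9, adjusted p = 0.028, and 0.074 with a replicate block), with the same numbers adjusted over the list alone. p53 targets were higher in 14 of 22 (16 adjusted over the list alone, adjusted p = 4.1e-06), with SPATA18 at 89.2 ± 8.76. Uterine contraction genes were higher in 10 of 16 (12 and 1 lower adjusted over the list alone, adjusted p = 4.1e-06), with EDNRB at 6.09 ± 3.56, and WNT genes were higher in 13 with 3 lower of 23 (15 and 3 adjusted over the list alone, adjusted p = 0.00052), with SFRP1 at 95.3 ± 36.6 and LGR5 at a log2 difference of 7.87. Chondrocyte genes (6 higher and 1 lower of 26; 7 and 1 adjusted over the list alone, adjusted p = 0.046, and 0.14 with a replicate block) included FMOD at 102 ± 13.6. With an estimated correlation the lists given here without that value ran from 0.087 to 0.37. Leukocyte genes were not called (1 higher and 2 lower of 12, adjusted p = 0.50). edgeR called 4308 genes, 2927 higher and 1381 lower, and DESeq2 3159 higher and 2393 lower. The count was 6854 with a replicate block, 1913 without FDC replicate 1, 2537 without FDC replicate 2 and 2853 without ESF replicate 1.

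**Figure D3:**
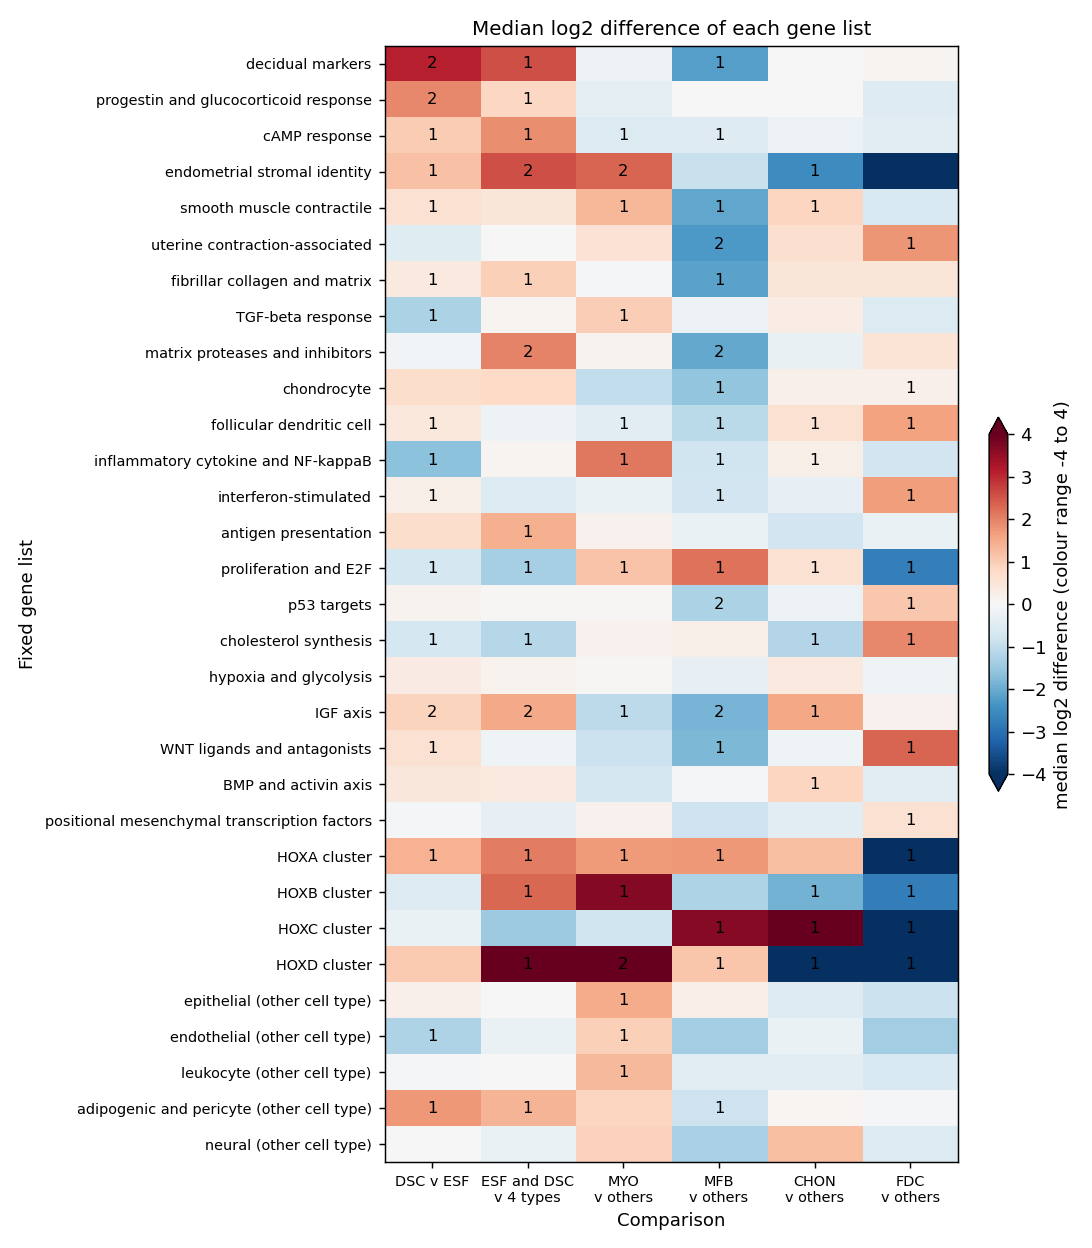
Heat map of the median log2 difference of each gene list in the 6 comparisons, with floors for groups at 0, and with 1 for a camera adjusted p under 0.05 and 2 where that held with an estimated correlation. Proliferation genes had a median of 2.19 in MFB and -2.75 in FDC.

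The last questions were which type lies nearest to ESF and how much expression is shared. FDC was nearest after DSC, at a distance (1 minus the Spearman correlation) of 0.120 ± 0.00747, then CHON at 0.129 (single pairs 0.120 to 0.139), MYO at 0.131 ± 0.00239 and MFB at 0.166 ± 0.00446, against 0.0667 between ESF and DSC. From DSC, FDC lay at 0.117, CHON at 0.152, MYO at 0.174 and MFB at 0.195. MYO was nearer than CHON by the Euclidean distance, without MYO replicate 1, without CHON replicate 1, and with only replicate 2 of the 4 types (0.129 against 0.138). MFB was not last in every setting. By 1 minus the Pearson correlation of log2 CPM it lay at 0.2403, against 0.2407 for CHON and 0.2498 for MYO. With no filter on TPM, MFB and MYO were level at 0.0733. The margin of FDC over CHON was 7.03% with an SD of 8.48 over 8 combinations of single libraries, of which 6 favoured FDC. With only replicate 1 of the 4 types CHON was nearer and the margin was -4.01%, and with only replicate 2 it was 18.2%. A neighbour-joining tree joined DSC with ESF in 100% of bootstraps over genes and these with FDC in 99.8%, but with only replicate 2 CHON joined FDC in 54.2%. Bootstraps over genes do not cover differences between cultures.

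**Figure D4:**
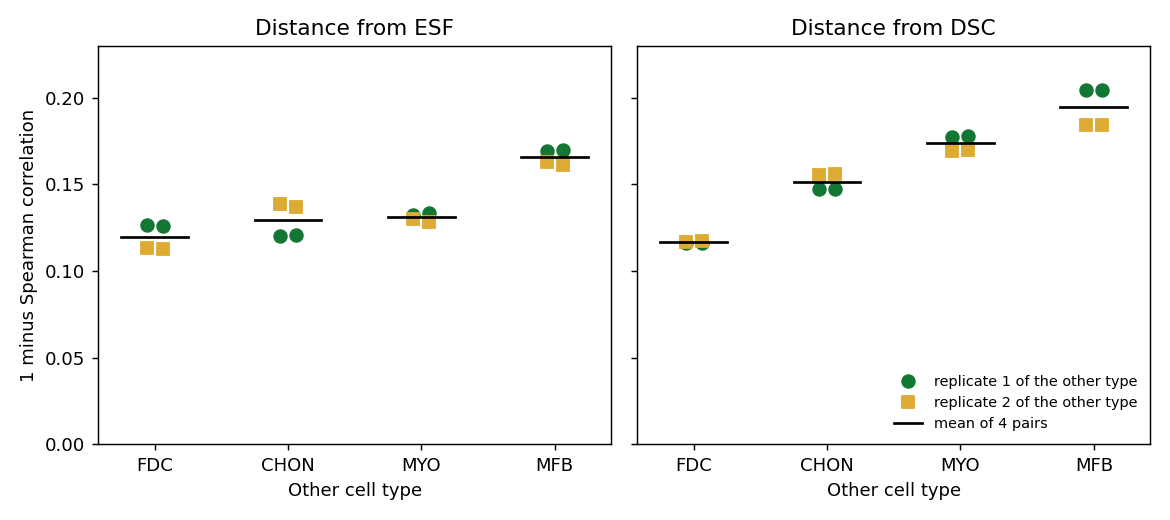
Distance of ESF (left) and DSC (right) to FDC, CHON, MYO and MFB as 1 minus the Spearman correlation, with circles for replicate 1 and squares for replicate 2 of the other type and lines for means. ESF lay at 0.120 from FDC and 0.166 from MFB.

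Of 21999 protein-coding genes 8470 were expressed in all 6 types and 485 in 1 type only: 161 in MYO, 93 in FDC, 83 in CHON, 64 in MFB, 47 in DSC and 37 in ESF. ESF and DSC come from 1 line, and a gene expressed in both counts for neither, so their numbers cannot be ranked against the others. The counts per type depended on single libraries: without MFB replicate 1 MFB had 166, as many as MYO then had, without CHON replicate 1 CHON had 138, and without FDC replicate 2 FDC had 142. Among them were the actin-bundling LCP1 in MYO (524), LUZP2 in MFB (48.3), the neuronal NRN1 in CHON (51.6), the matrix gene DPT in FDC (157), MMP10 in ESF (291) and RASL11B in DSC (58.1). Across genes the DSC minus ESF difference correlated at 0.147 with the difference of FDC from the other 3 types, at -0.0989 with that of MYO, -0.0658 with that of MFB and -0.00918 with that of CHON. The sign for MFB turned in the genes called between DSC and ESF (0.0121), and that for CHON without MFB replicate 2 (0.00682), without FDC replicate 1 (0.00435), with the recovered reads (0.0232) and with only replicate 2 (0.0554). Genes are not independent, so no p-value is given.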

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

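The test of the CHON columns and the test of splits were chosen after the results were seen. The deposited count column of CHON replicate 2, with a total of 21430992, was not used in the comparisons and drew attention as a signal in a column outside the main measurement. No gene had more counts in it than in CHON replicate 1. Its chi-square per gene against that library was 0.339, and 20 simulated draws of 49.7% of the reads of CHON replicate 1 gave 0.337, so the column may be a random part of those reads. The TPM column of the same sample gave back 55481950 counts of a different library. No biological explanation was tested.

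Replicate 2 of MYO, MFB, CHON and FDC differed from replicate 1 in the same genes: 34.5% of 13475 genes had the same sign in all 4 types, where 12.5% would by chance, and 381 differed over 2-fold the same way. Of the 351 of these with gene models, 37.6% overlapped a gene on the opposite strand against 13.5% of the 12831 others, an odds ratio of 3.87 (95% interval 3.10 to 4.83). A prediction written before this test was met, so reads may have been assigned with regard to strand in some of these libraries and without it in others. The odds ratio pools the 195 genes higher and the 186 lower in replicate 2, so by itself it does not tell strand from another cause. GC content as the whole cause was excluded by a test written before, since the mean correlation between types was 0.598 before and 0.596 after a GC trend was removed. The mean shift itself had a Spearman correlation of -0.469 with GC content, so a part played by GC is not excluded. Without overlapping genes the correlation between types was still 0.510, so strand could be only part of the cause. No biological explanation was tested.

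For the endometrial comparison, 100 splits of the 10 libraries into 3 and 7, the real one among them, were tried with a fit of 2 groups. In that fit 2 of the 100 gave as many called genes as the real split, counting the real one with 538, and the highest other gave 553. The highest other was replicate 2 of MYO, MFB and FDC, which follows the replicate pattern. In the fit of 6 groups with a replicate block the real comparison called 9306 genes. That fit was not made for the other splits, so its count cannot be set against theirs. The splits do not decide on chance, because libraries of 1 type, and ESF and DSC of 1 line, are not independent, and most splits that part them call 0 genes.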

How the results depend on the processing

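The settings with a replicate block among 4 types, recovered CHON reads, the CHON replicate 2 column, single replicates, and DSC or ESF counted otherwise were chosen after the results were seen. With 1 or 2 libraries per type, spread is poorly known, and simulated 2-fold changes were recovered in 3% (DSC against ESF) to 29% (endometrial) of genes. Under other settings, of the tests of the 431 named-gene results 11667 stayed the same, 402 grew weaker, 323 stronger and 14 reversed, and of those of 90 list results 1580 stayed, 231 grew weaker, 2 stronger and 3 reversed. The replicate block among 4 types ended only the list calls printed in the report. It made PGR, HOXA10, HOXA11, HOXA3, EMX2, WT1, MYOCD, CALD1, BST1, OAS1, MCM6, UHRF1, STARD4, EGFL7, ABCC9, KCNJ8, MCAM and PPARG pass in DSC against ESF, DHCR7, HMGCR and DHCR24 in CHON and HOXB3 in FDC. In CHON it also made the HOXA cluster (adjusted p from 0.054 to 0.032) and the hypoxia and glycolysis list (from 0.093 to 0.032) pass. It changed no other call of a list or named gene. The block on all types ended the calls of COL14A1 in DSC against ESF, CALB2 in MFB and LMOD1 in CHON. Where no reason is given below, the cause was not tested.

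Genes called in DSC against ESF (636) became 1771 with DESeq2, 1026 with limma-voom, 1760 with no low-count filter, 1107 with a replicate block on all types, 10615 with only ESF and DSC in the fit, and 2039 with the block among 4 types. It was 1784 with recovered CHON reads and that block, 1302 with the CHON replicate 2 column, 2198 with DSC as 2 libraries, 0 with ESF also as 1 library, and 10767 and 10759 with only replicate 1 or 2 of the 4 types. With DESeq2 and ESF also as 1 library, 2611 genes were higher and 2639 lower in MFB, and 2160 and 2555 in the endometrial comparison. The endometrial share also turned with no low-count filter (3492 and 3619) and with only replicate 1 (7654 and 7966). With single replicates of the 4 types and with only ESF and DSC, the spread rested on the close ESF libraries alone. The 0 was from edgeR, which then had 1914 genes at an unadjusted p under 0.05, where DESeq2 called 878. Leaving out single libraries gave 0 (ESF 1 or ESF 2) to 832. With the block among 4 types, recovered reads and that block, ESF also as 1 library, and only replicate 1 or 2, the endometrial comparison (5140) gave 9306, 9653, 2529, 15620 and 14433, and 8102 with DSC as 2 libraries (leave-outs 2437 without ESF 1, 2458 without ESF 2, to 5747). MYO (4169) gave 6768, 7250, 2776, 12661 and 11906 (leave-outs 2371 without MYO 2, 2674 without MYO 1, 2758 and 2757 without ESF 1 and 2, to 4593), and MFB (4971) gave 7529, 7782, 3211, 12818 and 11441 (leave-outs 2915 without MFB 1, 3185 and 3212 without ESF 1 and 2, to 5248). CHON (1348) gave 2083, 4201, 867, 10163 and 11094, and 2091 with DESeq2, 2488 with no filter, 2546 with recovered reads, 3507 with the CHON replicate 2 column and 2035 with recovered reads in place of the first library (leave-outs 859 without ESF 2, 870 without ESF 1, to 1465). FDC (4308) gave 6854, 6850, 13099 and 10939, leaving aside ESF also as 1 library, which gave 2887 (leave-outs 1913 without FDC 1, 2537 without FDC 2, 2853 without ESF 1, to 5000).

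With an estimated correlation the lists called were 3 in DSC against ESF, 3 in the endometrial comparison, 2 in MYO, 4 in MFB, 0 in CHON and 0 in FDC, against 17, 14, 14, 18, 11 and 13. With recovered reads and the block they were 11 in DSC against ESF, 8 in MYO and 5 in CHON, and MYO had 9 with a block on all types and 8 with the block among 4. Leaving out 1 library also ended list calls that the block among 4 types kept, those of smooth muscle in MYO without MYO 2, and of interferon-stimulated genes in MFB and proliferation genes in CHON without MFB 1. Leave-outs gave 15 to 18, 13 to 15, 9 (without MFB 2) to 15, 16 to 19, 8 to 13 and 12 to 15.

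FDC stayed nearest to ESF under every planned distance, with a margin over CHON of 0.538% to 11.3%. With only replicate 1 of the 4 types this margin was -4.01% (CHON nearer), and 18.2% with only replicate 2 (leave-outs 0.706 to 13.2). It was taken over CHON in every setting. Where MYO or MFB was nearer than CHON, the lead of FDC over the next type was smaller than this margin. Genes expressed in all 6 types were 9694 at a TPM of 1 and 6052 at 10, and in 1 type only 544 and 444. The last count was 829 with only replicate 1 and 872 with only replicate 2, where fewer libraries had to pass (leave-outs 8478 to 8560 and 491 to 601).

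The correlation of the DSC minus ESF difference with CHON (-0.00918) was -0.0321 in called genes, -0.0146 by Pearson, -0.0169 with a CPM filter, and reversed to 0.0232 with recovered reads, 0.0327 with these in place of the first library, 0.0554 with only replicate 2, 0.00682 without MFB 2 and 0.00435 without FDC 1 (leave-outs -0.0262 to 0.00682). That with FDC (0.147) was 0.253, 0.116 and 0.200 in the same first 3 settings, 0.148 with the block, 0.142 and 0.144 with recovered reads added or in place, and 0.177 and 0.110 with only replicate 1 or 2 (leave-outs 0.104 to 0.168). That with MFB (-0.0658) reversed to 0.0121 in called genes and was -0.0233, -0.0824, -0.0685 with the block, -0.0713 with recovered reads, and -0.114 and -0.0205 with only replicate 1 or 2 (leave-outs -0.0966 to -0.0241). That with MYO (-0.0989) was -0.251, -0.0783, -0.147, -0.102 and -0.0919 with recovered reads, and -0.101 and -0.108 with only replicate 1 or 2 (leave-outs -0.108 to -0.0748).

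CRISPLD2 reversed to -0.90 in the endometrial comparison with ESF alone. In CHON, with recovered reads in place of the first library and with only replicate 2, the log2 differences reversed to -2.56 and -2.97 for ACTG2, -2.72 and -2.19 for KCNMB1, -3.41 and -3.16 for IL1B, -0.28 and -0.19 for MCM5, -0.22 and -0.11 for MCM3 and -0.19 and -0.34 for TYMS, and to 0.0571 for MME in the first of these. With recovered reads in place, the CHON lists of smooth muscle (adjusted p = 0.54), inflammatory (adjusted p = 0.97) and proliferation genes (adjusted p = 0.20) also reversed.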

Other observations

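TERT was near 0 in FDC and MFB and high elsewhere. ESF, DSC and CHON come from hTERT lines, so their TERT cannot be read as a trait of the cell type. No line is given for MYO, and the source of its TERT was not tested. Its TPM was 1051 and 185 in the MYO libraries, 1128 and 591 in CHON, 372 and 350 in ESF, 272 and 272 in DSC, 0.923 and 1.21 in MFB, and 0.00548 and 0 in FDC. Genes expressed in 1 type only included, in MYO, the adaptor FYB (165), in MFB, FOXG1 (31.4), in CHON, the forkhead gene FOXQ1 (43.6), in FDC, the integrin ITGA8 (178) and the matrix protein THBS4 (147), and in ESF, DCSTAMP (36.4). These were chosen after their values were seen. Between types outside the endometrium, MYO and MFB lay at a distance of 0.109 and CHON and FDC at 0.119, against 0.187 between MYO and FDC. Replicates lay at 0.0393 in MYO, 0.0358 in MFB, 0.0420 in CHON and 0.0215 in FDC, and at 0.00117 in ESF and 0.00105 in DSC.

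Of the following tests of MFB, the one on growth was chosen after the results were seen and those on p53 and RB were written before. In MFB the proliferation genes were higher and the p53 targets lower than in the other types, with a median of -1.26 for the p53 targets. Faster growth as the whole cause could not be told. In MYO, where proliferation genes were also higher, the median of p53 targets was 0.0419 (SE 0.208), but it was -0.315 (SE 0.235) with MFB left out of the reference types. In FDC proliferation genes had a median of -2.75 and p53 targets of 1.07, with 14 of 22 called higher. MFB is among the reference types of FDC too, and no FDC value without it was computed. The FDC values therefore do not decide on growth. Low p53 activity could not be told: a second list of 25 p53 targets had a median of -0.0410 in MFB, with 14 lower, 9 called lower and 2 called higher, and 0.271 of random lists were as low. Low RB activity may play a part, since CDKN2A, which RB represses, had at least 130 CPM in MFB against at most 27.0 in any other type, as predicted. This test used 1 gene and named no outcome for low p53 activity, so it does not tell RB from p53. SV40 large T binds both proteins, and the effect of its removal was not analysed here.

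Over the 381 genes of the replicate pattern the ESF and DSC libraries lay at a median of 22.2% to 26.9% of the way from replicate 1 to replicate 2. This was looked at after the pattern was seen, and the odds ratio of 3.87 for overlap could fit libraries prepared or counted in more than 1 way.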
